A study of Canis lupus familiaris with 22 samples.

How the data were processed

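The series held 22 RNA-seq libraries from the eyes of 7 mixed-breed dogs. In the first set, 4 dogs (18-2, 18-6, 18-7 and 18-9) each gave a macular retina, a peripheral retina, a macular RPE/choroid and a peripheral RPE/choroid library, 16 in all. In the second set, 3 other dogs (1, 2 and 3) each gave 2 macular RPE/choroid libraries, one eye sampled with the retina left on and the fellow eye sampled after the retina had been peeled off, 6 in all. Every library was assigned to its group and its dog from the labels.

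Per the labels' protocols, column-purified, DNase-treated total RNA was made into libraries with a directional Illumina kit. The deposited files held raw read counts, as whole numbers, for 30951 dog Ensembl gene identifiers in each library. The submitters' processing notes name Trimmomatic 0.39, FastQC 0.11.8, HISAT2 2.1.0, SAMtools and featureCounts 2.0.0, without giving what each was used for. The genome build, the annotation release, the strand setting of the counting and the handling of duplicate reads are not given in the sources used here. Without the strand setting, it is unknown how reads of overlapping and antisense genes were assigned, and the values of single identifiers are uncertain to that extent.

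The files did not pair identifiers with names. The reference table used here (assembly UU_Cfam_GSD_1.0) held 0 Ensembl entries, and 0 of the 30951 identifiers matched a symbol in it. Genes are therefore given by identifier, at most 2 that rose and 2 that fell in each comparison. The marker, pathway and disease gene lists, the rod transcript share and the photoreceptor-based alternatives that had been fixed before the data were examined could not be computed, since each needs gene symbols.

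Comparisons, tests, covariates, the rule for named genes and the alternatives were fixed before the data were examined, unless stated otherwise. Counts were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with TMM normalization, low-count genes removed by filterByExpr with the group as its argument, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. All p-values of single genes and all adjusted p-values of single genes are from this test unless another is named. Each of the 6 comparisons was fitted on its own groups with the dog as a block. The interaction was fitted on the 16 libraries of the first set with each dog's tissue as a block, and tested whether the difference between macula and periphery differed between tissues. That fit treated the regional differences in the retina and in the RPE/choroid of a dog as independent and did not pair them. Standard errors of log2 fold changes were taken from the size of the fold change and the F statistic. Identifiers were named by size of log2 fold change among genes past the threshold, with a mean log2 CPM of at least 1 and the same direction in every dog. The last condition was not applied to the interaction. The rule had also required a symbol and allowed more genes, and both parts were dropped after the identifiers had been found to match no symbol. CPM, computed from the deposited counts, was scaled by total counts. For a group without a single count, a fold is given as a lower bound computed against 3 counts over the pooled libraries of that group. Ratios with 1 to 3 counts in a group have exact binomial 95% intervals. Such intervals and floors cover counting error only.

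Because the planned gene lists could not be used, gene groups were defined from the data, after they had been seen. Each of 15577 genes was placed by its tissue contrast, averaged over both regions, in a single fit of the 16 libraries of the first set. This contrast is balanced between macula and periphery. Retina-preferential genes (1692) were at least 4-fold higher in retina, RPE/choroid-preferential genes (2035) were at least 4-fold higher in RPE/choroid, both past the threshold, and shared genes (9448) had fitted values that differed by under 2-fold. A further 2402 genes lay between. The 200 genes with the largest fold in each direction and a mean log2 CPM of at least 1 formed a retina list and an RPE/choroid list, whose summed CPM was taken as a level per library. These groups came from the same libraries as the regional comparisons and are not independent evidence there. They are independent of the 3 dogs of the second set. Groups were tested with camera (limma 3.58.1) with a preset correlation of 0.01, again with an estimated correlation, and with fry. The comparison of retina on with retina off also used 2 lists of 200 genes taken by a rule fixed beforehand from the macular tissue comparison.

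List levels were compared within dogs with exact two-sided sign-flip permutation tests, and overlaps of calls with Fisher's exact test. DESeq2 1.42.0 was run as an alternative, together with RLE normalization, no low-count filter, no dog block, each dog left out in turn and a single fit over 16 libraries. Duplicate deposition was checked by a chi-square test between libraries of each group over genes with at least 50 counts. Among 30 pairs, the statistic per degree of freedom ran from 3.90 to 59.6, and no pair agreed within sampling noise. The dog names in the labels pair the libraries. Deviations from the group means correlated between libraries of one dog at 0.388 to 0.485 for the regions of the retina, at 0.368 to 0.560 for the regions of RPE/choroid, at -0.0851 to 0.103 between tissues in the macula, at 0.0792 to 0.189 between tissues in the periphery and at -0.0455 to 0.603 between fellow eyes. The correlation was highest with the own dog in 4 of 4 dogs for either regional pairing and for the tissues in the periphery. That held in only 1 of 4 dogs for the tissues in the macula. Between fellow eyes it held in 2 of 3 dogs, with dog 2 (-0.0455) as the exception.

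The test was tried on simulated counts with the real dispersions, dog effects and library sizes, with 200 genes changed by known folds. Before the change, all libraries had the fitted level of the second group, which was periphery, RPE/choroid or retina off. In the interaction, both tissues had the regional difference of RPE/choroid. The changed genes were drawn from those with a real mean log2 CPM of at least 1, in a single simulation per comparison. Genes under that mean were not tried. Of the genes changed 2-fold, 86.6% were recovered in the retina comparison, 64.2% in the RPE/choroid comparison, 59.7% in the interaction and 11.9% in the comparison of retina on with retina off, where 84.8% of the genes changed 4-fold were recovered. In the tissue comparisons, 43.3% (macula) and 64.2% (periphery) of the genes changed 2-fold were recovered. A drawn gene with few counts in RPE/choroid was simulated at that low level, where recovery is hardly possible. These shares therefore do not measure recovery at the real levels. Unchanged genes were called too, 32 of them in the simulated retina comparison beside 172 changed ones and 15 in the simulated comparison of retina on with retina off beside 64. Unchanged genes made up 5.69% to 19.0% of the calls over the 6 simulated comparisons, above the nominal 5%. Far fewer genes were changed here than were called in the real regional and tissue comparisons, so this share need not carry over to them. No simulated gene was called in the wrong direction.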

Results

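Gene expression was measured by RNA-seq in the retina and in the underlying retinal pigment epithelium with choroid (RPE/choroid) of dogs, in the macula and in the periphery. The macula is the central region of highest visual acuity, the RPE is the epithelial cell layer that supports the photoreceptors, and the choroid is the vascular layer behind it. Each of the 4 groups from the first 4 dogs (macular retina, peripheral retina, macular RPE/choroid and peripheral RPE/choroid) held 4 libraries, and the groups sampled with the retina on or off held 3 libraries each. Total counts per library ran from 2690847 (peripheral RPE/choroid, dog 18-6) to 7845325 (retina-off RPE/choroid, dog 3). Group means, in M counts, were 6.11 ± 0.87 in macular retina, 5.61 ± 0.67 in peripheral retina, 6.19 ± 1.14 in macular RPE/choroid and 5.28 ± 1.94 in peripheral RPE/choroid (SD, n = 4 each). They were 4.26 ± 0.12 with the retina on and 5.35 ± 2.22 with the retina off (SD, n = 3 each).

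Tissue separated the libraries on the first principal component of log2 CPM, which held 73.8% of the variance. The second, with 8.0%, separated 5 of the 6 libraries of the second set of dogs, at scores of 30.9 to 83.8, from the RPE/choroid of the first 4 dogs, at -52.1 to -15.0. The retina-off library of dog 3 had a score of -35.6. Pearson correlations across genes lay between 0.962 and 0.984 among retina libraries, between 0.912 and 0.977 among RPE/choroid libraries of the first 4 dogs, and between 0.623 and 0.715 across these tissues.

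**Figure D1:**
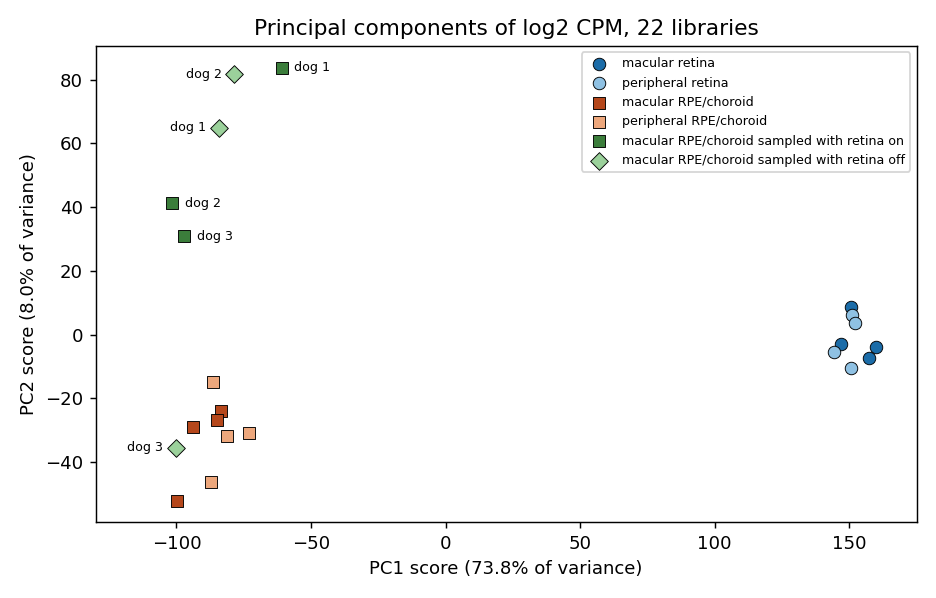
Scores of the 22 libraries on the first 2 principal components of log2 CPM, 1 point per library, with symbols for the 6 groups and dog names beside the libraries sampled with the retina on or off. The 8 retina libraries lie at the right, and the retina-off library of dog 3, at -35.6 on the second component, lies among the RPE/choroid libraries of the first 4 dogs.

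The first comparison asked how the macular retina differed from the peripheral retina of the same dogs. In the macula, 1765 genes were higher and 954 were lower, of 14392 tested (edgeR, n = 4 dogs). Most differences were small. The called genes had a median absolute log2 fold change of 0.53, and 344 higher and 98 lower genes differed by at least 2-fold. Genes expressed preferentially in the retina were called most often, with 532 of 1687 (31.5%) higher and 149 (8.83%) lower in the macula and a median log2 fold change of 0.16. These counts were 339 and 49 without the dog block, 348 and 90 with DESeq2 and 150 and 20 in a single fit over 16 libraries. With 1 dog left out, 532 were higher and 251 lower without dog 18-2, 455 and 87 without dog 18-6, 371 and 77 without dog 18-7, and 402 and 97 without dog 18-9. Among RPE/choroid-preferential genes detected in the retina, 180 of 1167 (15.4%) were higher and 123 (10.5%) lower, with a median of 0.04. For these genes the counts were 77 and 34 without the dog block, 86 and 61 with DESeq2, 74 and 53 in the single fit, 104 and 72 without dog 18-6, 139 and 55 without dog 18-7, and 98 and 89 without dog 18-9. Of the genes shared between tissues, 659 of 9271 (7.11%) were higher and 492 (5.31%) lower, with a median of -0.03. The upward shift of the retina-preferential genes against all others had an adjusted p of 1.78e-07 by camera over 3 groups, but an adjusted p of 0.128 with an estimated correlation. By fry, which asks only whether the group moved one way on balance, the adjusted p was 0.0325. Camera placed the shared genes below the others (adjusted p = 0.00180, and 0.128 with an estimated correlation), although their mean log2 fold change was above 0, at 0.00337. RPE/choroid-preferential genes did not stand apart (adjusted p = 0.765 by camera).

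The identifiers with the largest rise were ENSCAFG00000013947, with a log2 fold change of 3.21 ± 0.44 (SE, adjusted p = 0.00187), and ENSCAFG00000015909, with 2.93 ± 0.39 (SE, adjusted p = 0.00157). ENSCAFG00000013947 averaged 27.3 ± 29.4 CPM in the macula and 2.58 ± 2.74 CPM in the periphery (SD, n = 4 each). ENSCAFG00000015909 averaged 78.5 ± 84.8 CPM and 9.16 ± 10.3 CPM (SD, n = 4 each). The wide spread of both lay between dogs, and every dog had the higher value in the macula. The largest falls were those of ENSCAFG00000011211, at -4.63 ± 0.25 (SE, adjusted p = 5.62e-05), and ENSCAFG00000015475, at -3.51 ± 0.26 (SE, adjusted p = 1.78e-04). They averaged 0.809 ± 1.09 and 2.65 ± 1.64 CPM in the macula and 20.5 ± 26.9 and 29.3 ± 12.7 CPM in the periphery (SD, n = 4 each). The count of called genes was 1224 without the dog block, 1381 with DESeq2 and 760 in a single fit over 16 libraries, and 1706, 1519 and 1721 with dogs 18-6, 18-7 and 18-9 left out. Without dog 18-2 it was 3765, with 1894 higher and 1871 lower, so that the excess of higher over lower genes was nearly gone without this dog. Without dog 18-6, the log2 fold change was 2.60 for ENSCAFG00000013947 and 2.25 for ENSCAFG00000015909. The 2 risen identifiers passed the threshold neither without the block nor in the single fit. Their log2 fold changes were then 3.35 and 3.07 without the block, and 3.31 and 2.90 in the single fit.

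The same question was asked of the RPE/choroid. In the macula, 1175 genes were higher and 755 lower than in the periphery, of 14352 tested (edgeR, n = 4 dogs). The called genes had a median absolute log2 fold change of 0.63, and 326 higher and 201 lower genes differed by at least 2-fold. The balance of directions turned with DESeq2, which called 1144 genes higher and 1319 lower, and without dog 18-7, with 1287 higher and 1396 lower. Here the RPE/choroid-preferential genes were called most often, with 439 of 2034 (21.6%) higher and 126 (6.19%) lower and a median log2 fold change of 0.20. These counts depended on single dogs, with 30 higher and 6 lower without dog 18-2, 80 and 17 without dog 18-9 and 122 and 33 without dog 18-6. They were 125 and 20 without the dog block, 443 and 223 with DESeq2, 338 and 72 in a single fit over 16 libraries and 276 and 49 with the level of the retina list as a covariate. The median of these genes ran from 0.15 to 0.26 with each dog left out in turn. Their upward shift had an adjusted p of 1.14e-05 by camera, an adjusted p of 0.207 with an estimated correlation, and an adjusted p of 0.0178 by fry. Retina-preferential genes detected in RPE/choroid had 74 of 771 (9.60%) higher and 47 (6.10%) lower, with an adjusted p of 0.772 by camera. Their median was -0.08, with 0.00 without dog 18-7 and -0.20 without dog 18-2. Their counts were 10 and 1 without dog 18-2, 23 and 9 without dog 18-6, 26 and 9 without dog 18-9, 32 and 5 without the dog block, 79 and 79 with DESeq2, 134 and 92 in the single fit and 48 and 13 with the covariate. Shared genes were evenly divided, with 420 higher and 420 lower of 9276 (camera adjusted p = 0.0127 downward, and 0.322 with an estimated correlation). The summed level of the 200-gene RPE/choroid list was 1.22-fold higher in the macula (mean log2 difference 0.28 ± 0.12, SD, n = 4 pairs) and higher in 4 of 4 dogs. The exact two-sided permutation test gave the smallest p that 4 pairs allow, which is above 0.05, and an adjusted p of 0.5 over 4 tests.

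**Figure D2:**
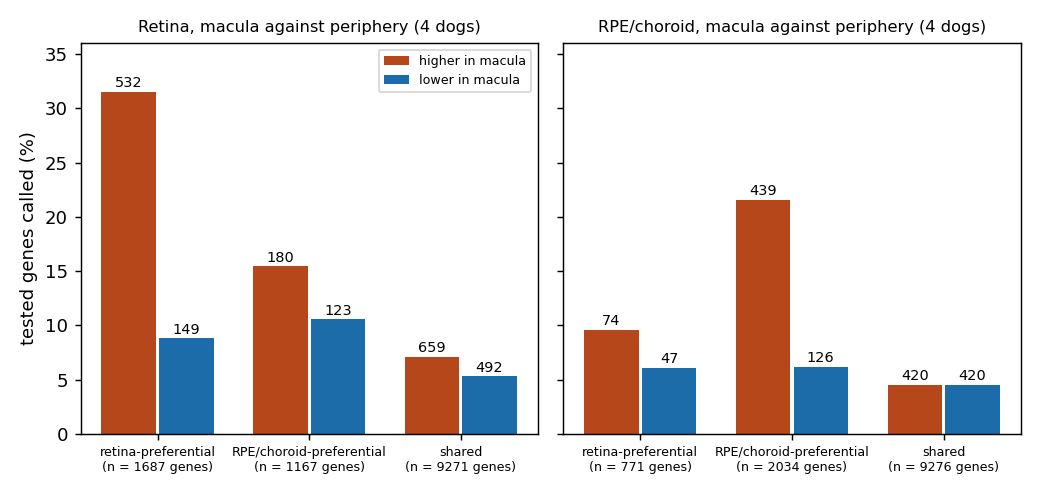
Percent of tested genes called higher (left bar of each pair) or lower (right bar) in the macula, for retina (left panel) and RPE/choroid (right panel), by the tissue in which the genes were preferentially expressed. Numbers above the bars are gene counts. In retina 532 retina-preferential genes were higher, and in RPE/choroid 439 RPE/choroid-preferential genes were higher.

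ENSCAFG00000002586 and ENSCAFG00000016038 were the identifiers with the largest fitted rise in macular RPE/choroid (adjusted p = 0.0135 and 0.0106). Each had only 2 counts in all 4 peripheral libraries. Both counts of ENSCAFG00000002586 were in dog 18-9, and no peripheral count is left without it. The pooled ratio was 103.7 (95% counting interval 28.4 to 861) for ENSCAFG00000002586, at 11.3 ± 11.1 CPM in the macula, and 57.6 (15.6 to 480) for ENSCAFG00000016038, at 5.25 ± 2.53 CPM (SD, n = 4 each). Both ratios depended on single dogs. For ENSCAFG00000002586 the ratio was 64.3 without dog 18-2 and 58.4 without dog 18-6, and at least 61.7 without dog 18-9. For ENSCAFG00000016038 it was 106.8 without dog 18-6 and 30.0 without dog 18-9. The largest falls were those of ENSCAFG00000028728, at -5.93 ± 0.43 (SE, adjusted p = 0.00438), and ENSCAFG00000015051, at -5.77 ± 0.39 (SE, adjusted p = 0.00409). ENSCAFG00000028728 averaged 149 ± 126 CPM in the periphery and 2.40 ± 1.32 CPM in the macula, and ENSCAFG00000015051 averaged 32.4 ± 17.4 and 0.639 ± 0.653 CPM (SD, n = 4 each). Without dog 18-7, the log2 fold change of ENSCAFG00000015051 was -6.36. The count of called genes depended on single dogs, with 74 genes when dog 18-2 was left out, 239 without dog 18-9 and 359 without dog 18-6. It was 349 without the dog block and 881 with the level of the retina list as a covariate, an alternative chosen after the data had been seen. The number of genes with an unadjusted p under 0.05 (edgeR) moved less. It was 5238 in the main fit, 4135 without dog 18-2, 3347 without dog 18-9 and 3918 without dog 18-6. Both risen identifiers lost their call without dog 18-2, and ENSCAFG00000002586 also lost it without dog 18-6.

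Whether the regional difference itself differed between the tissues was tested with an interaction term. The difference between macula and periphery was more positive in retina for 1502 genes and more positive in RPE/choroid for 1491, of 15577 tested (edgeR, n = 4 dogs). Among the 1502, 366 were called in neither tissue on its own, 577 were called higher in the macula in retina alone, 401 were called lower in the macula in RPE/choroid alone, and 135 were called in opposite directions in the separate tests of the tissues, higher in macular retina and lower in macular RPE/choroid. Among the 1491, 487 were called in neither tissue on its own, 484 were called higher in macular RPE/choroid alone, 373 lower in macular retina alone, and 97 were lower in macular retina and higher in macular RPE/choroid. In both breakdowns, a gene left out of a tissue's own test for low counts was counted as not called there. The median interaction log2 value was 0.25 for retina-preferential genes (210 called more positive in retina and 123 in RPE/choroid, of 1692) and -0.25 for RPE/choroid-preferential genes (188 and 286 of 2035). Neither group stood apart from the others (adjusted p = 0.132 for both by camera). Shared genes had a median of -0.02 and a mean of 0.01, with 784 and 799 called of 9448 (adjusted p = 0.782 by camera and 0.0478 by fry, both downward). ENSCAFG00000028728, with the fall in macular RPE/choroid given above, had 1.90 ± 0.50 CPM in macular and 1.25 ± 1.12 CPM in peripheral retina (adjusted p = 0.00253 for the interaction). ENSCAFG00000000052 had 128 ± 22 CPM in macular and 18.1 ± 8.90 CPM in peripheral RPE/choroid, against 0.103 ± 0.206 and 0.838 ± 1.22 CPM in the retina (adjusted p = 0.0115). ENSCAFG00000007599 had 16 ± 1.26 CPM in macular and 4.78 ± 1.42 CPM in peripheral retina, 0.539 ± 0.71 CPM in peripheral RPE/choroid and no count in macular RPE/choroid (adjusted p = 0.00648). ENSCAFG00000038248 had 6.50 ± 4.21 CPM in macular and 1.5 ± 1.21 CPM in peripheral RPE/choroid, 0.814 ± 0.326 CPM in peripheral retina and no count in macular retina (adjusted p = 0.00413, all SD with n = 4). The number of interaction calls was 705 without the block, 1181 without dog 18-6 and 812 without dog 18-9. ENSCAFG00000007599 lost its call without dog 18-7 and ENSCAFG00000000052 without dog 18-9.

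The regional calls of the tissues were also set against each other among the 13243 genes tested in both. Across these genes, which are not independent replicates, the regional log2 fold changes correlated at -0.07 (Pearson) and -0.04 (Spearman). Called in both tissues were 476 genes, 51.3% of them in the same direction. The count higher in the macula of both tissues was 194, against 111.6 for independent lists (Fisher's exact test, p = 1.54e-15 and adjusted p = 6.14e-15 over 4 tests), and the count lower in both was 50 against 46.3 (adjusted p = 0.533). Calls in opposite directions were also more frequent than for independent lists. Higher in macular retina and lower in macular RPE/choroid were 135 genes against 76.7 (Fisher's exact test, p = 2.52e-11, adjusted p = 5.04e-11), and lower in macular retina and higher in macular RPE/choroid were 97 against 67.4 (p = 2.25e-04, adjusted p = 3.00e-04). With a threshold of 0.01 for the adjusted p of the genes, 11 were higher in both against 4.11 (Fisher's exact test, adjusted p = 0.00955) and 2 lower in both against 0.288 (adjusted p = 0.0432). Higher in macular retina and lower in macular RPE/choroid was then 1 gene against 0.763, without an excess (Fisher's exact test, adjusted p = 0.545), and the reverse held for 5 against 1.55 (adjusted p = 0.0385). Higher in both were 43 genes without the block, and 20, 42 and 28 with dogs 18-2, 18-6 and 18-9 left out. Lower in both were 2, 2, 5 and 5 in the same order. The RPE/choroid calls also fell in each of these fits, for example from 1175 to 63 higher genes without dog 18-2. Expected counts were not computed for these fits, so the smaller counts do not show a weaker overlap.

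Retina and RPE/choroid were compared within each region. In the macula, 4711 genes were higher in retina and 4745 higher in RPE/choroid, of 14997 tested, and in the periphery 4828 and 4872 of 14729 (edgeR, n = 4 dogs). In the macula, 1641 genes were at least 4-fold higher in retina and 1808 at least 4-fold higher in RPE/choroid. In the periphery the counts were 1437 and 1755. Tissue fold changes in the regions correlated at 0.94 (Pearson) and 0.91 (Spearman) across 14568 genes. Of the 7787 genes called in both regions, 99.5% differed in the same direction and 36 in opposite directions. ENSCAFG00000004910, at 56.1 ± 8.22 CPM, and ENSCAFG00000019049, at 43.3 ± 2.98 CPM in macular retina (SD, n = 4 each), had no count in macular RPE/choroid and were at least 468-fold and 359-fold higher in retina. ENSCAFG00000030630, at 29.0 ± 29.6 CPM, and ENSCAFG00000011945, at 31.4 ± 13.7 CPM in macular RPE/choroid (SD, n = 4 each), had no count in macular retina and were at least 247-fold and 254-fold lower there. In the periphery, ENSCAFG00000010093 (70.3 ± 15.5 CPM) and ENSCAFG00000011694 (54.4 ± 11 CPM) had counts in retina and none in RPE/choroid, and were at least 491-fold and 386-fold higher in retina. ENSCAFG00000005313 (32.5 ± 8.91 CPM) and ENSCAFG00000031939 (24.2 ± 22.5 CPM) had counts in peripheral RPE/choroid and none in peripheral retina, and were at least 255-fold and 217-fold lower in retina (SD, n = 4 each). Leaving out 1 dog lowers such bounds, also because the floor then rests on fewer libraries. Without dog 18-2 or dog 18-7, the bound for ENSCAFG00000030630 was 125-fold and 131-fold. Without dog 18-9, it was 157-fold for ENSCAFG00000011945 and 96.2-fold for ENSCAFG00000031939. Without dog 18-7, it was 321-fold for ENSCAFG00000010093, 238-fold for ENSCAFG00000011694 and 154-fold for ENSCAFG00000005313. Adjusted p-values of these 8 identifiers ran from 3.07e-05 to 0.00181.

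The second set of dogs compared macular RPE/choroid sampled with the retina left on with that of the fellow eye, sampled after the retina had been peeled off. No gene of 14076 passed the threshold in edgeR (n = 3 dogs, smallest adjusted p = 0.99987), and 84 genes had an unadjusted p under 0.05, where 703.8 would be expected by chance. DESeq2 also called 0 genes, with 62 at an unadjusted p under 0.05. The square root of the common dispersion was 28.6%, against 15.8% for the regional comparison of RPE/choroid. Retina-preferential genes had a median log2 fold change of 0.07 (744 genes) and RPE/choroid-preferential genes one of -0.02 (1867 genes), with adjusted p of 0.383 and 0.324 by camera over 5 groups. Both medians turned with single dogs. They were -0.26 and 0.06 without dog 1, 0.37 and -0.16 without dog 2, and -0.03 and 0.01 without dog 3. Without the dog block, in alternatives chosen after the data had been seen, they were -0.58 and -0.06 with the retina-on library of dog 1 left out, and -0.01 and 0.04 with the retina-off library of dog 3 left out. Shared genes (9149) had a median of 0.01 and a mean of -0.02, and camera placed them above the others without passing the threshold (adjusted p = 0.324). Of the 200 macular retina genes chosen by the rule fixed beforehand, 5 had enough counts to be tested, and of the 200 macular RPE/choroid genes 178 had. Of the members of both lists, 0 were called over all genes and 0 when adjusted over the list alone (camera adjusted p = 0.383 and 0.0587). All retina-on libraries came from right eyes and all retina-off libraries from left eyes, so that eye side and sampling cannot be told apart. With dog 2 left out, the one dog whose retina list was lower with the retina on, 83 genes were called, 80 of them higher with the retina on, and 71 of these 80 were retina-preferential. The log2 difference of the retina list was 2.29 in dog 1 and 0.61 in dog 3. How far each of these dogs carried the calls was not tested.

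The amount of retinal transcript in each RPE/choroid library was measured as the summed CPM of the 200-gene retina list, in percent of its mean in retina libraries. In the first 4 dogs it was between 0.294% and 0.562%, with the caveat that the list was chosen on these libraries. It did not differ by more than the spread between dogs from macula to periphery (mean log2 difference -0.03 ± 0.68, SD, n = 4 pairs, higher in the macula in 1 of 4 dogs, exact permutation test p = 0.875 and adjusted p = 1 over 4 tests). The mean turned to 0.22 without dog 18-7 and to 0.01 without dog 18-9, and was -0.33 without dog 18-2. In the second set, the level was 4.06% with the retina on and 0.831% with it off in dog 1, 0.213% and 0.723% in dog 2, and 0.321% and 0.210% in dog 3. The mean log2 difference of 0.38 ± 2.04 (SD, n = 3 pairs) was within the spread between dogs, with 2 of 3 dogs higher with the retina on (exact permutation test p = 0.75, where 3 pairs cannot go below 0.25). It was -0.58 without dog 1 and 1.45 without dog 2. The RPE/choroid list differed by -0.03 ± 0.23 on the log2 scale (SD, n = 3 pairs, exact permutation test p = 1).

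**Figure D3:**
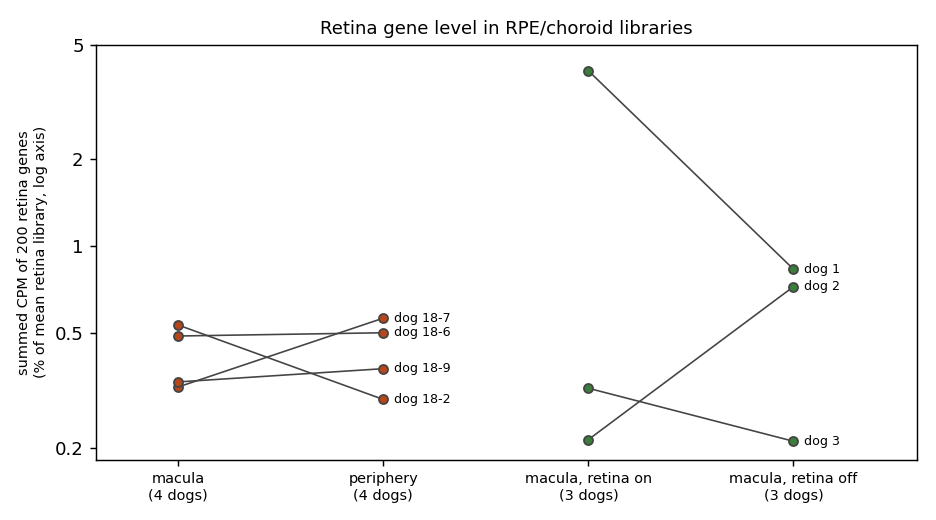
Summed CPM of the 200-gene retina list in each RPE/choroid library, as a percent of the mean retina library on a log axis, with lines joining the libraries of 1 dog. The 8 libraries of the first 4 dogs lie between 0.294% and 0.562%, and dog 1 has the highest value, 4.06%, with the retina on.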

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

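The list level among the tests below was chosen after the data had been seen, and the other tests before. A library far from the other 3 of its group was looked for in 63 sets of 4 values, 7 of which had one, where chance would give about 3.15. No explanation was tested for these values.

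In peripheral retina, the summed CPM of the 200-gene RPE/choroid list was 208 in dog 18-9 and 59.3 to 74.4 in the other 3 dogs. The same library had 24.5 CPM of ENSCAFG00000015909, higher in macular retina, against 2.67 to 6.22 in the other peripheral retinas. Dog 18-7 stood apart in ENSCAFG00000011211, lower in macular retina, with 2.43 CPM in the macula (0.161 to 0.442 in the others) and 60.8 CPM in the periphery (4.72 to 10.4 in the others). Dog 18-7 also had the highest level of ENSCAFG00000005313 in peripheral RPE/choroid, 45.8 CPM against 27.1 to 29.2. In peripheral RPE/choroid, ENSCAFG00000002586 had 0.305 CPM in dog 18-9 and no count in the other 3 dogs. In macular retina, ENSCAFG00000000052 had 0.412 CPM in dog 18-6 and no count in the other 3 dogs. Both of these rest on 2 counts.

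The regional difference itself differed between retina and RPE/choroid, by the interaction term, for 2993 genes. The named identifiers among them were ENSCAFG00000028728 (adjusted p = 0.00253), ENSCAFG00000038248 (adjusted p = 0.00413), ENSCAFG00000007599 (adjusted p = 0.00648) and ENSCAFG00000000052 (adjusted p = 0.0115), all from edgeR.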

How the results depend on the processing

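The alternatives with the retina list as a covariate, with retina-preferential genes or single libraries left out, and all those on gene groups and list levels, were chosen after seeing the data. The planned rod covariate, the fit without photoreceptor genes, the single-gene rod share and the tests of the planned gene lists were not run, because the identifiers could not be matched to symbols. The tissue comparisons stayed within 1.5 times their counts, 9456 and 9700, under every alternative run. So did every comparison under RLE normalization and without the low-count filter. The regional counts did not. Without the dog block, the main design's pairing of libraries of 1 dog, retina calls fell from 2719 to 1224, RPE/choroid calls from 1930 to 349 and interaction calls from 2993 to 705, and genes higher or lower in the macula of both tissues fell from 194 to 43 and from 50 to 2. Overlap counts fall with the calls they come from, and no expected counts were computed under the alternatives without the block or a dog. Without the block, retina on against off still gave 0 genes. DESeq2 called 1381 genes in the retina, of which 1365 were among the 2719, and 2463 in RPE/choroid, where 46.4% were higher in the macula against 60.9% in edgeR. A single fit over 16 libraries called 760 in the retina. With the retina list as a covariate, 881 were called in RPE/choroid, of which 814 were among the 1930. With a threshold of 0.01, 11 genes were higher and 2 lower in both tissues. With each dog left out, counts ran from 1519 to 3765 in the retina, from 74 (dog 18-2) to 2683 (dog 18-7) in RPE/choroid and from 812 to 2532 for the interaction, overlaps from 20 to 140 (higher in both) and from 2 to 38 (lower in both), and retina on against off from 0 to 83 (dog 2). Fewer libraries enter these fits. The cause was otherwise not tested. Without the block, retina on against off also gave 0 genes after removing the retina-off library of dog 3 or the retina-on library of dog 1. Of 180 values under alternatives for 20 results of 19 named identifiers, 171 kept direction and call, 9 lost the call and 0 reversed. These identifiers had been named for large folds past the threshold in the same data and, except in the interaction, for the same direction in every dog. Reversals were therefore hardly possible, and the tally is no independent support. Depth limits what low genes can show, since 3 counts over a group of 4 libraries correspond to 0.121 to 0.142 CPM.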

Other observations

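The tests of carried-over retinal RNA and of depth were written before their results were seen, and the tests of a common sampling effect, another dog, repeated reads, other splits and expression bins were chosen after.

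In dog 1, retina genes were 4.88-fold higher in the RPE/choroid sampled with the retina on (1826 counts against 404 over the 200-gene list, 95% counting interval 4.38 to 5.45). RNA of the retina may have been carried over into that sample. Of the 57 list genes with at least 5 counts in this dog, 96.5% were higher with the retina on (exact 95% interval 87.9 to 99.6), and the excess corresponded to 3.39% of the retina level for the 100 more abundant genes and 2.13% for the 100 less abundant ones. By the same measure, 15.0% of 20 genes were higher with the retina on in dog 2 (3.21 to 37.9) and 57.9% of 19 genes in dog 3 (33.5 to 79.7). These intervals treat the genes as independent, although the genes of a dog come from the same libraries. They do not measure a spread between samples. A common effect of the sampling cannot be told apart, since the mean log2 difference over the 3 dogs was 0.38 with an SD of 2.04 between dogs (2.29, -1.76 and 0.61 in dogs 1, 2 and 3). An exchange of the labels of the libraries of dog 2 could give its opposite direction and stays open. A difference between the eyes of dog 1 before sampling stays open as untested.

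The retina-off library of dog 3, the deepest of all, correlated more closely with the macular RPE/choroid of the first 4 dogs (mean r 0.958 across genes) than with its own set (0.914), a difference of 0.0447, whereas the other 5 libraries of its set had differences of -0.0458 to -0.0137. Depth is argued against, since thinning it to 4368948 counts left the difference at 0.0446 (0.0443 to 0.0450 over 5 draws). Sampling with the retina off was not tested as an explanation, and the retina-off libraries of dogs 1 and 2 had differences of -0.0330 and -0.0443. The deviations of the libraries of dog 3 from their group means correlated at 0.485, highest with the own dog among the dogs of the set. Whether the retina-off library of dog 3 could come from another dog cannot be told apart. The check used 90 genes that differed between dogs of the first set, which were all the candidates. Over these genes, its distance to the other library of dog 3 was 1.09 times that to its nearest other dog (dog 18-9). For the retina-on library of dog 3 this ratio was 1.02, so neither library of dog 3 lay nearest to its own dog. Of the 14 RPE/choroid libraries, 12 did, with those of the first set having served to choose the genes. Among the 12 were 4 of 4 libraries of dogs 1 and 2, which had no part in that choice. For the retina-off library of dog 3, 1000 random gene lists of matched level gave a median ratio of 1.22 (95% of them 0.881 to 1.68). Its ratio of 1.09 lay within that range, with 25% of the random lists below it. The chosen genes thus brought it neither clearly nearer to its dog nor clearly farther from it than random genes did. Genes that mark dogs would draw a library nearer to its own dog. A ratio within the range therefore does not speak against another dog, nor does it show one. A library batch was not tested, because the labels give none.

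The most abundant genes held a small share of the counts. The most abundant gene took 0.0933% to 0.153% of a library's counts and the top 100 genes took 4.91% to 6.72%. A candidate explanation is the loss of repeated reads of abundant genes before counting, by which counts of such genes would rise less than in proportion to depth and their fold changes would be compressed. Within groups of RPE/choroid, the slope of log2 counts on log2 library total was 0.833 for the top 100 genes and 1.08 for 1000 genes of middling abundance, a difference of -0.24 that stayed between -0.25 and -0.21 with each dog left out. In the retina the difference was -0.22 but turned to 0.597 without dog 18-6, the shallowest, so that the loss of reads cannot be told apart from other causes, and no biological explanation was tested.

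Whether another grouping of the libraries would give as many genes was examined by refitting other splits. Because the libraries are paired by dog, the real split was compared with the splits that part the libraries of every dog. In the comparisons of 4 dogs these are 8 splits, too few for a share under 0.05. Of these 8, 1 (the real one) reached the real count, which was 2719 in the retina, 1930 in RPE/choroid, 2993 for the interaction, 9456 for the tissues in the macula and 9700 in the periphery, and the highest other gave 0 in each. The splits other than the real one turn the difference around in some of the dogs. A real difference then adds to the residual spread of those fits, so the counts of 0 do not show what chance would give. The other splits that could be fitted left both libraries of some dogs on one side. In the region and tissue comparisons, the dog block absorbs such dogs, so only the parted dogs bore on the test. In the interaction, these splits set whole dogs against each other for part of the libraries, or, in 3 splits, for all of them. The highest counts of these other splits were 12 in the retina and 626 in RPE/choroid, and 0 in the other 3 comparisons. The splits with 12 and 626 genes kept the real contrast of macula and periphery in dogs 18-6 and 18-9. These counts are therefore not those of a wrong grouping. For retina on against off, 4 splits part the libraries of every dog, also too few, with 0 genes in the real one and 39 in the highest other, which exchanged the libraries of dog 2.

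The overlap of regional calls between tissues was recomputed within 10 bins of mean expression. It was 194 against 118.5 expected for genes higher in both tissues, 135 against 76.3 for higher in retina and lower in RPE/choroid, 97 against 64.4 for the reverse, and 50 against 47.7 for lower in both. The exact Mantel-Haenszel test gave adjusted p of 1.69e-12, 2.43e-11, 4.89e-05 and 0.699 in that order.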
